A study of Mus musculus with 34 samples.

How the data were processed

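Gene expression was measured by RNA sequencing in soleus and plantaris of female mice aged 24 or 6 months, either sedentary or after 8 weeks of progressive weighted wheel running (PoWeR). The deposited table holds expected counts (expected_counts): the authors' estimated read counts per gene, not normalized, a part of them not whole numbers. Per the submitters' processing notes, reads were handled with STAR 2.7.3a, Partek and DESeq2 on mm10, with no order or role stated for each tool. The table has 23011 genes in 34 libraries, each gene with a summed count of at least 10. Expected counts were rounded to whole numbers before the models were fitted. Gene coordinates come from the deposited table, where they match an mm10 (GRCm38) annotation.

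Groups were taken from the labels: muscle, age and training. The titles of the aged plantaris libraries say soleus while their source name says plantaris, and the source name was followed. Aged replicates carry the numbers of their labels, and young replicates were numbered in the order of deposition, so young numbers pair nothing. The names of the young soleus libraries and of the libraries labelled young plantaris share numbers, which were not used as pairs. The labels do not say that the libraries of a group come from separate animals, so p-values measure the spread between samples. The libraries labelled young plantaris were kept in the group of their label although their myosin genes are soleus-like, since no group was changed on the basis of values.

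Each muscle's 17 libraries were fitted together with a mean per group, and the muscle by PoWeR interactions were fitted within the 18 aged and the 16 young libraries. edgeR 4.0.16 in R 4.3.3 was used with TMM factors, filterByExpr by group (minimum count 10, minimum total count 15), robust dispersions and the quasi-likelihood F test. Genes with a Benjamini-Hochberg adjusted p under 0.05 over all genes tested were called. Log2 fold changes are PoWeR against sedentary or aged against young, and interactions are aged minus young effect or soleus minus plantaris effect. CPM values of single genes are counts scaled to a common library total, where each library's sum of counts was first adjusted by its TMM factor. They are given as mean and SD. Standard errors of log2 fold changes come from the fit.

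For each comparison of training or age, the genes named are the 8 largest rises and the 8 largest falls among called genes with a mean CPM of at least 5 in either group and no overlap between the libraries of the groups. Members of the gene lists described are named by the largest absolute change, up to 4 called members per list, or up to 2 by the smallest p where none was called. For interactions the 5 smallest adjusted p in each direction are eligible. The rule, the gene lists, the tests and most alternatives were fixed before the data were examined.

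A set of 40 gene lists covering fibre type, metabolism, stress, growth and cell type markers was tested with camera in limma 3.58.1 on voom values with a preset correlation between genes of 0.01, and again with an estimated correlation. Lists with fewer than 3 tested genes were left out. fry was run beside it. Members were also counted when adjusted over the list alone. Myosin heavy chain shares were compared by exact two-sided permutation tests of the difference of means in scipy 1.17.1, with adjustment over 16 tests. Correlations between comparisons are across genes, with the overlap that independent lists would give. The covariance of age and training effects was compared with that from 20 simulations of unchanged groups and with the aged sedentary libraries divided between the comparisons. Figures were drawn with matplotlib 3.10.9 and numpy 2.4.6 under Python 3.11.15.

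The alternatives were DESeq2 1.42.0, limma with quality weights, RLE factors, no filter on low counts, only the groups compared (all 8 groups for an interaction), the replicate numbers of the labels as a block, genes over 5 CPM, and each library left out in turn. Chosen after seeing the data were offsets for GC content and transcript length (loess span 0.5, prior count 1), a term for libraries with an rRNA repeat share under 0.7%, and the omission of 2 aged plantaris libraries. Each gene-level count was also compared with up to 100 other splits of the same libraries. The fits were tested on simulated data with 200 changed genes, in which edgeR recovered 91 of 100 changes of 2-fold in the aged soleus design, 76 in aged plantaris, 88 in young soleus and 82 in the design of the libraries labelled young plantaris. For changes of 1.5-fold it recovered 49, 29, 41 and 22. Over the 10 simulated comparisons 2.63 to 6.31% of edgeR's calls were false, and 10.3 to 20.9% of those of DESeq2. Total counts were 15237626 to 26250461 per library, and the spread between replicates exceeded counting error in every group. No column of per-sample values was left out.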

Results

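RNA from the soleus, a slow postural muscle of the hindlimb, and from the plantaris, its fast neighbour, was sequenced from female mice aged 24 months (aged) and 6 months (young). PoWeR is progressive weighted wheel running, in which mice run voluntarily on a wheel that carries added weight; it lasted 8 weeks and ended with a 24 h wheel lock and an overnight fast. Age-matched sedentary mice were the controls. The 34 libraries fall into 8 groups, with 5 libraries in each aged sedentary group and 4 in every other group. Total counts ran from 15237626 to 26250461 per library, and 23011 genes had a summed count of at least 10. Replicates of a group varied more than counting error alone would give, with a smallest chi-square per degree of freedom of 4.90, so the spread between libraries and not the depth set the precision.

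Myosin heavy chains place the muscles apart and were read first as a check of the labels. Myh7, the heavy chain of slow fibres (mm10 chromosome 14, 54970684 to 54994626), had 23040 ± 2793 CPM (counts scaled to a common library total; SD, n = 5) in aged sedentary soleus and 455 ± 385 CPM (n = 5) in aged sedentary plantaris. Myh4, the heavy chain of the fastest fibres (chromosome 11, 67238029 to 67260446), had 352 ± 696 CPM in that soleus group and 53302 ± 11441 CPM in that plantaris group. The libraries labelled young plantaris did not follow the aged plantaris. Their Myh7 was 22353 ± 2944 CPM (n = 4) in the sedentary and 24914 ± 5458 CPM (n = 4) in the PoWeR group, beside 18799 ± 1967 and 23896 ± 4673 CPM in young soleus. Their Myh4 was 27.5 ± 10.1 and 19.3 ± 5.24 CPM, beside 21.2 ± 4.87 and 20.7 ± 5.94 CPM in young soleus. All 8 libraries labelled young plantaris thus carry a soleus-like profile, and every direction drawn from them below is of the libraries labelled young plantaris.

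**Figure D1:**
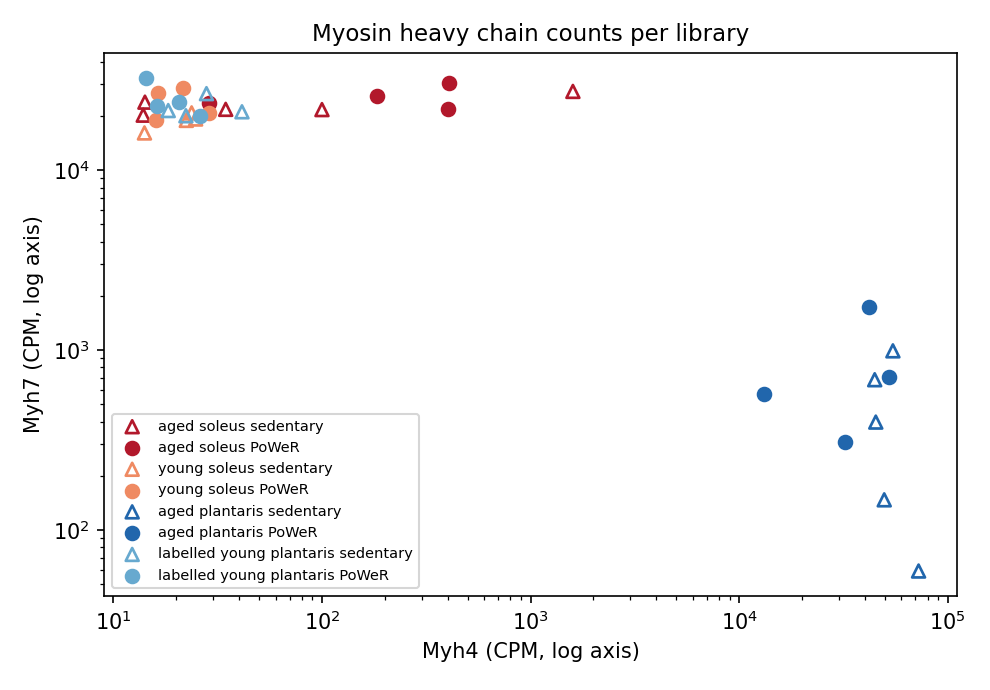
Myh4 (x axis) and Myh7 (y axis) in CPM on log axes, 1 point per library; open triangles are sedentary and filled circles PoWeR. The 9 aged plantaris libraries lie at the lower right, and the 8 libraries labelled young plantaris lie among the soleus libraries at the upper left.

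Library composition also differed between groups. Mitochondrially encoded genes held 22.3 ± 0.775% of counts (SD, n = 4) in young sedentary soleus and 15 ± 3.54% in young PoWeR soleus. The share was 14 ± 0.552% (n = 5) against 11.6 ± 1.25% (n = 4) in aged soleus, 11.3 ± 1.33% against 15.8 ± 3.57% in aged plantaris, and 15.4 ± 2.65% against 12.6 ± 1.46% in the libraries labelled young plantaris. The rRNA repeat gene CT010467.1 held from 0.242 to 3.71% of counts in the libraries labelled young plantaris, where sedentary replicate 3 and PoWeR replicates 1, 2 and 4 were under 0.7%. Young soleus PoWeR replicate 3 was the only other library under 0.7%, at 0.422%.

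**Figure D2:**
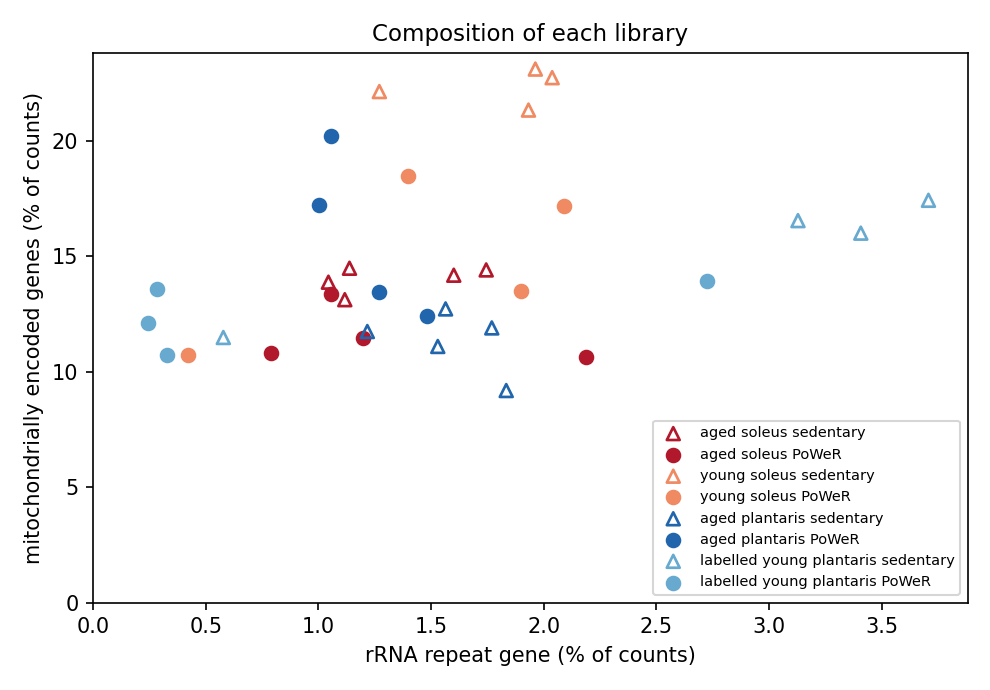
Share of counts on the rRNA repeat gene (x axis, percent) and on mitochondrially encoded genes (y axis, percent), 1 point per library; open triangles are sedentary and filled circles PoWeR. Young sedentary soleus has the 4 highest mitochondrial shares, and 5 young libraries lie at the far left.

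The effect of late-life training was compared first in the aged soleus. There, Nrcam, a neuronal cell adhesion molecule (chromosome 12, 44328885 to 44601964), rose from 1.12 ± 0.398 CPM (SD, n = 5) to 6.88 ± 3.88 CPM (n = 4). Fasn, the fatty acid synthase, rose from 11.1 ± 2.52 to 35.8 ± 8.89 CPM. Padi2, a peptidylarginine deiminase (chromosome 4, 140906344 to 140952586), fell from 139 ± 10.1 to 67.1 ± 4.68 CPM. Of 11 denervation response genes 2 rose and of 22 fatty acid use genes 2 fell, and neither list passed camera with an estimated correlation (adjusted p = 0.494 for each). The log2 fold changes were 2.60 ± 0.40 (SE) for Nrcam, 1.68 ± 0.26 for Fasn and -1.07 ± 0.17 for Padi2, with edgeR adjusted p values of 0.0065, 0.0097 and 0.00681.

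In total, 128 of 14934 genes passed edgeR's quasi-likelihood test in aged soleus, 70 higher and 58 lower with PoWeR. Among called genes with no overlap between the libraries of the groups and a mean of at least 5 CPM in either, the largest rises after Nrcam and Fasn were those of Rrm2, a subunit of ribonucleotide reductase (1.54), Sh2d4a (1.3), Tmem86a (1.29), Prkag3, a regulatory subunit of AMP-activated kinase (1.29), the Notch ligand Dll1 (1.26) and the protease inhibitor Serpinb1a (1.24). On the same basis the largest falls were those of the lipoprotein receptor Olr1 (-2.52), the MAP kinase phosphatase Dusp1 (-1.64), Dhrs9 (-1.58), the magnesium channel Trpm6 (-1.22), Atp1b4 (-1.18), the Wnt inhibitor Dkk2 (-1.11), Padi2 and the muscle-secreted peptide gene Ostn (-0.99). As the rule for naming required, all 4 PoWeR libraries lay on the same side of all 5 sedentary libraries in each of these genes.

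Of 11 denervation response genes, 2 rose and 9 did not pass the test over all genes; adjusted over the list alone, 8 rose. Gadd45a, a growth arrest gene (log2 2.96 ± 0.58, SE), and Runx1, a transcription factor of denervated muscle (2.49 ± 0.52), were those 2. The list's mean log2 fold change was 1.42, with a camera adjusted p of 7.22e-07 and an adjusted p = 0.494 with an estimated correlation. The rise was not in every PoWeR library: relative to the sedentary mean, the list's mean log2 value was 1.84, 1.99, -0.19 and 0.77 in replicates 10, 12, 14 and 15. Of 22 fatty acid use genes, 2 fell, the beta-oxidation enzymes Acaa2 (-0.77 ± 0.15) and Acadm (-0.58 ± 0.12); adjusted over the list alone, 16 fell. The mean of that list was -0.35 (camera adjusted p = 2.14e-15). Nuclear genes of oxidative phosphorylation averaged -0.31 with 0 of 29 past the test by edgeR and 7 lower when adjusted over the list alone, and the 13 mitochondrially encoded genes averaged -0.40 with 0 past it in either way. The TCA cycle list averaged -0.23 and the glycolysis list -0.17, and both passed camera with the preset correlation. Of 9 satellite cell genes Myod1, a myogenic transcription factor, rose (1.05 ± 0.22), and the list averaged 0.43. The atrophy signalling list averaged 0.24 and the glucocorticoid and fasting list 0.50, with 0 members of either past the gene-level test. All 9 of these lists passed camera, and their smallest adjusted p = 0.494 with an estimated correlation.

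The count of 128 was 378 with DESeq2, 521 with limma and quality weights, 229 with the groups outside the comparison left out of the fit and 216 with a term for the rRNA repeat share. It was 36 without PoWeR replicate 12, 52 without sedentary replicate 12 and 63 without sedentary replicate 15. Gadd45a and Runx1 lost their calls in most fits that left out a library. Among other genes named above, Dhrs9 kept its call in 3 of 9 such fits. Dll1, Trpm6, Acadm and Myod1 kept theirs in 4 of 9.

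In aged plantaris few single genes passed, and no list passed camera with an estimated correlation (smallest adjusted p = 0.172). Tjp1, which encodes the tight junction protein ZO-1, rose (log2 0.83 ± 0.12, SE; edgeR adjusted p = 0.0277; n = 5 and 4), as did the transcriptional regulator Mecom (0.95 ± 0.17). The receptor gene Gpr157 fell (-0.94 ± 0.15). A further gene, B430218F22Rik, fell (-3.81 ± 0.61) and is named here after its values were seen. Of 12 endothelial markers 0 passed edgeR's test over all genes, and 10 were higher when adjusted over the list alone; their mean log2 fold change was 0.51.

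These 4 genes, 2 higher and 2 lower, were all that passed among 15280 tested in aged plantaris, while 1506 had an unadjusted p under 0.05. The endothelial list passed camera (adjusted p = 1.36e-09) but not with an estimated correlation (adjusted p = 0.172), and fry, which tests whether a list moves on balance in a single direction, gave an adjusted p = 0.0348. Smooth muscle and pericyte genes averaged 0.59, with 4 of 8 higher when adjusted over the list alone. Schwann cell genes averaged 1.35 (6 of 10) and adipocyte genes 1.56 (5 of 11) on the same basis, but their PoWeR libraries varied widely: the myelin gene Mbp had 27.9 ± 33.1 CPM in PoWeR and 8.0 ± 3.0 CPM in sedentary libraries (SD, n = 4 and 5), with overlap between the groups. Slow fibre genes averaged 0.58, fast fibre genes -0.27 and glycolysis genes -0.30. Mitochondrially encoded genes averaged 0.56 and nuclear oxidative phosphorylation genes 0.26, opposite in sign to aged soleus; the soleus minus plantaris differences, -0.95 and -0.57, passed camera but not with an estimated correlation (smallest adjusted p of that interaction = 0.55). The matrix list averaged 0.42, fibro-adipogenic progenitor genes 0.43, angiogenic factors 0.41, neutrophil genes 2.45, mast cell genes 1.32, TCA cycle genes 0.13 and ribosome biogenesis genes -0.14. The neutrophil and mast cell means rest on few counts. The neutrophil gene S100a8 had 1.91 ± 1.48 CPM in PoWeR and 0.164 ± 0.145 CPM in sedentary libraries, and the mast cell gene Kit 1.68 ± 1.17 and 0.61 ± 0.362 CPM, each with overlap. All 16 of these lists passed camera, none with an estimated correlation (smallest adjusted p = 0.172), and every member count over all genes was 0.

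The count of 4 became 116 with DESeq2 and 0 without sedentary replicate 13 or 14, without PoWeR replicate 10, 12 or 15, and with only the 2 groups compared. It was 2 without sedentary replicate 15, 10 without sedentary replicate 16 and 2 with no filter on low counts. With the rRNA repeat term, which marks no aged library, it was 8. Leaving out sedentary replicate 16 and PoWeR replicate 12 together, chosen after seeing the data, also gave 8. In that fit the adipocyte, matrix and fibro-adipogenic lists turned negative, the slow fibre mean went to 0.06 and the endothelial mean was 0.49.

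**Figure D3:**
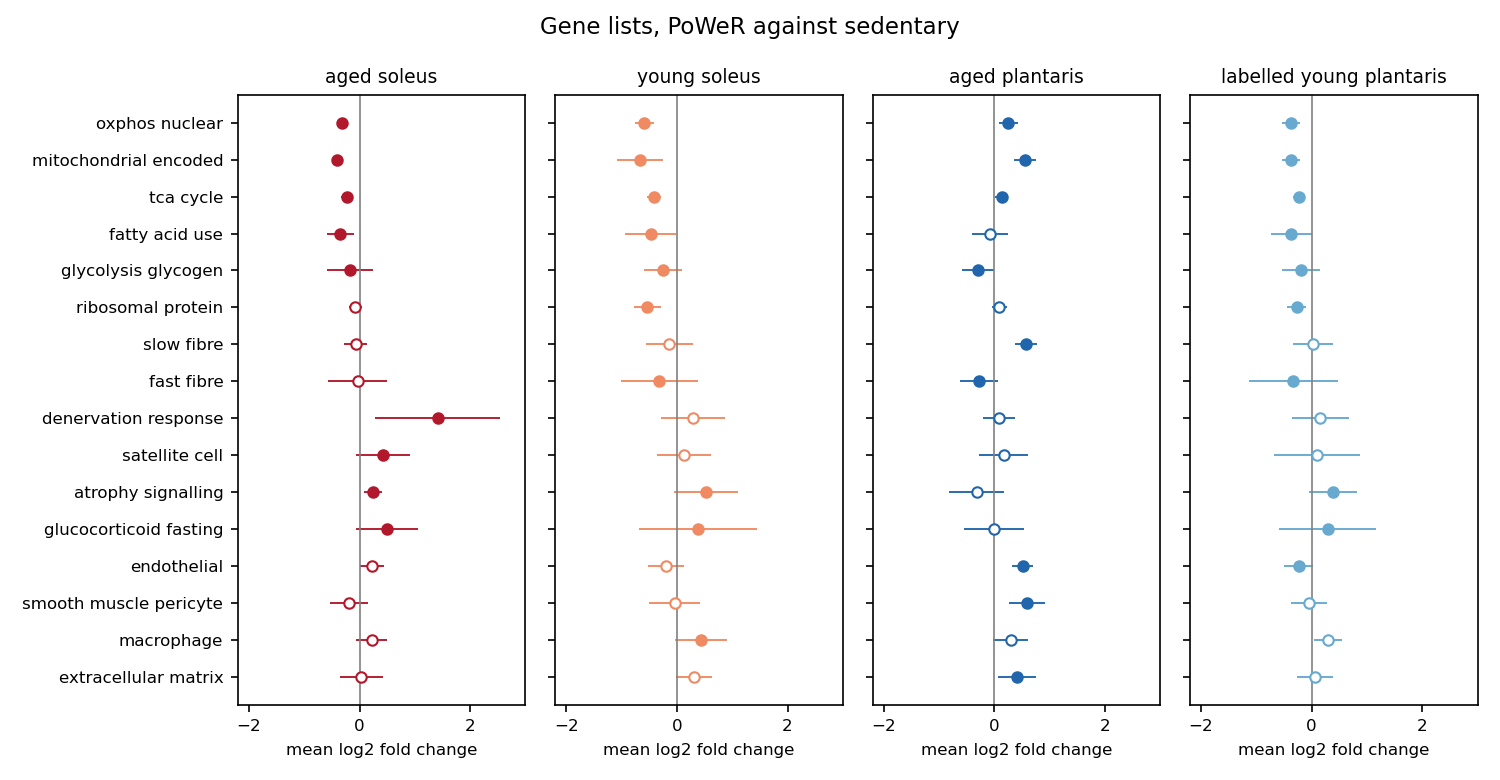
Mean log2 fold change of 16 gene lists (PoWeR against sedentary) in the 4 comparisons; bars are the SD over list members and filled points passed camera with the preset correlation. Oxidative phosphorylation genes average -0.31, -0.59 and -0.38 in aged soleus, young soleus and the libraries labelled young plantaris, and 0.26 in aged plantaris.

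In young soleus PoWeR went with lower expression of genes for respiration and for ribosomal proteins. Of 29 nuclear genes of oxidative phosphorylation 26 fell (mean log2 -0.59), as did 11 of 13 mitochondrially encoded genes (-0.67), 11 of 14 TCA cycle genes (-0.41) and 12 of 16 ribosomal protein genes (-0.53). Vegfa, the main angiogenic growth factor (chromosome 17, 46016993 to 46032369), fell from 140 ± 35.2 to 67.8 ± 4.73 CPM (SD, n = 4 and 4). Nrcam rose from 0.824 ± 0.18 to 7.31 ± 3.32 CPM, and Sh2d4a, an SH2 domain gene (chromosome 8, 68276567 to 68347699), from 5.57 ± 1.35 to 22.6 ± 7.33 CPM. These falls went with the fall of the mitochondrial share of counts from 22.3 to 15%.

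By edgeR 1920 of 14934 genes passed the test in young soleus, 891 higher and 1029 lower. The largest rises were those of the myosin binding protein gene Mybph (3.22), Nrcam (3.16 ± 0.44, SE; adjusted p = 0.00149), the methyltransferase gene Mettl21e (3.0), Fam171b (2.49), the ion channel gene Ano3 (2.16), the synaptic vesicle gene Sv2b (2.08), Sh2d4a (2.05 ± 0.26) and Galnt5 (1.81). The largest falls were those of Angptl4, an inhibitor of lipoprotein lipase (-2.33 ± 0.51), the immediate early gene Egr1 (-2.10), Slc22a2 (-2.09), the calcium pump inhibitor phospholamban, Pln (-1.96), the TWEAK receptor Tnfrsf12a (-1.80), Rrad (-1.73), Lrrc52 (-1.67) and the histone gene H2ac18 (-1.36). H2ac18 belongs to a cluster of similar histone genes whose reads are hard to tell apart. Vegfa changed by -1.01 ± 0.17 (adjusted p = 0.00445).

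Cytochrome oxidase subunits Cox8b (-0.88 ± 0.22), Cox7b (-0.87 ± 0.16) and Cox4i1 (-0.85 ± 0.19) and the succinate dehydrogenase subunit Sdhd (-0.74 ± 0.14) led the respiration list. Rps6 (-0.99 ± 0.20), Rps14 (-0.77) and Rpl18 (-0.74) led the ribosomal protein list. Of 22 fatty acid use genes 10 fell, among them Angptl4, Acaa2 (-0.76), Etfb (-0.64) and Hadh (-0.64). Among 15 fast fibre genes 5 fell, including the troponins Tnnc2 (-0.82), Tnni2 (-0.80) and Tnnt3 (-0.69), and 3 of 12 slow fibre genes fell, led by Myl3 (-0.82). Glycolysis genes fell in 5 of 18, antioxidant genes in 5 of 17, integrated stress genes in 4 of 9, heat shock genes in 3 of 15 and antigen presentation genes in 2 of 10. Of 12 atrophy signalling genes 3 rose, the ubiquitin ligase Fbxo32 (0.75 ± 0.15), the transcription factor Foxo3 (0.70) and Klf15 (0.67). Glucocorticoid targets Fkbp5 (1.28) and Klf9 (0.57) rose with Klf15 in a list of 10 in which Angptl4 fell. Klf15 kept its call in 1 of 8 fits that left out a library, and Fkbp5 in 2 of 8. The clock genes Per1 (0.71) and Tef (0.49) rose in a list of 17, and the macrophage receptor Mrc1 (1.20) in a list of 14. In total 15 of 38 lists passed camera, 4 higher and 11 lower, and 0 passed with an estimated correlation (smallest adjusted p = 0.356); fry passed 9.

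The 1920 genes were 602 without sedentary replicate 2, 1272 without sedentary replicate 3, 696 without PoWeR replicate 2 and 623 without PoWeR replicate 3. The rRNA repeat term, which marks only young PoWeR replicate 3 in the soleus fit, gave 620. With only the 2 groups compared the count was 358. That last fit left 3 of the 26 respiration calls, 1 of the 11 mitochondrially encoded and 3 of the 12 ribosomal protein calls. Among the largest changes, Mybph, Pln and Rrad kept their calls in 3 of 8 fits that left out a library.

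The libraries labelled young plantaris shared their leading genes with young soleus. Nrcam rose from 1.12 ± 0.373 to 10.5 ± 5.71 CPM (SD, n = 4 and 4) and Sh2d4a from 5.05 ± 0.70 to 20.5 ± 4.2 CPM. Padi2 fell from 145 ± 20.2 to 65.3 ± 12.7 CPM, and Vegfa from 121 ± 7.53 to 66.6 ± 4.04 CPM. Pln, the inhibitor of the slow calcium pump, fell by 1.77 on the log2 scale (SE 0.35), and the slow light chain gene Myl6b rose (1.0 ± 0.19).

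Here 34 of 15280 genes passed edgeR's test, 23 higher and 11 lower. The log2 fold changes were 3.21 ± 0.47 (SE) for Nrcam (adjusted p = 0.0106), 2.0 ± 0.26 for Sh2d4a (adjusted p = 0.00386), -1.17 ± 0.20 for Padi2 and -0.88 ± 0.16 for Vegfa. The other rises named by the rule were those of Ano3 (2.24), Sv2b (2.18), Ndrg4 (2.03), the olfactory-type G protein Gnal (1.72), the GABA transaminase Abat (1.54) and the sorting receptor Sort1 (1.14). The other falls were those of Efcab6 (-1.34), the thioredoxin inhibitor Txnip (-0.90), Atf5 (-0.76), Zfp770 (-0.76) and the nucleoporin Nup133 (-0.64). Of 29 oxidative phosphorylation genes 0 passed over all genes or adjusted over the list alone, although all 29 fold changes were negative and averaged -0.38. In all, 12 of 39 lists passed camera, 2 higher and 10 lower, with a smallest adjusted p = 0.738 with an estimated correlation.

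The PoWeR groups of these libraries also differ in the rRNA repeat share. With a term for it a single gene passed and 0 lists did. The count was 222 with DESeq2, 1369 with limma and quality weights and 87 with only the 2 groups compared. Without a sedentary replicate it was 7, 1, 227 and 2 (replicates 1 to 4) and without a PoWeR replicate 16, 1, 130 and 9. For Padi2 and Vegfa a lost call was not a lost difference between libraries of like share. Under 0.7%, Padi2 had 169 CPM in sedentary replicate 3 and 46.4 to 71.8 CPM in PoWeR replicates 1, 2 and 4. In the other libraries it had 119 to 148 CPM in sedentary and 73.2 CPM in PoWeR replicate 3. Vegfa had 120 against 63.7 to 65.7 CPM, and 116 to 132 against 72.6 CPM.

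**Figure D4:**
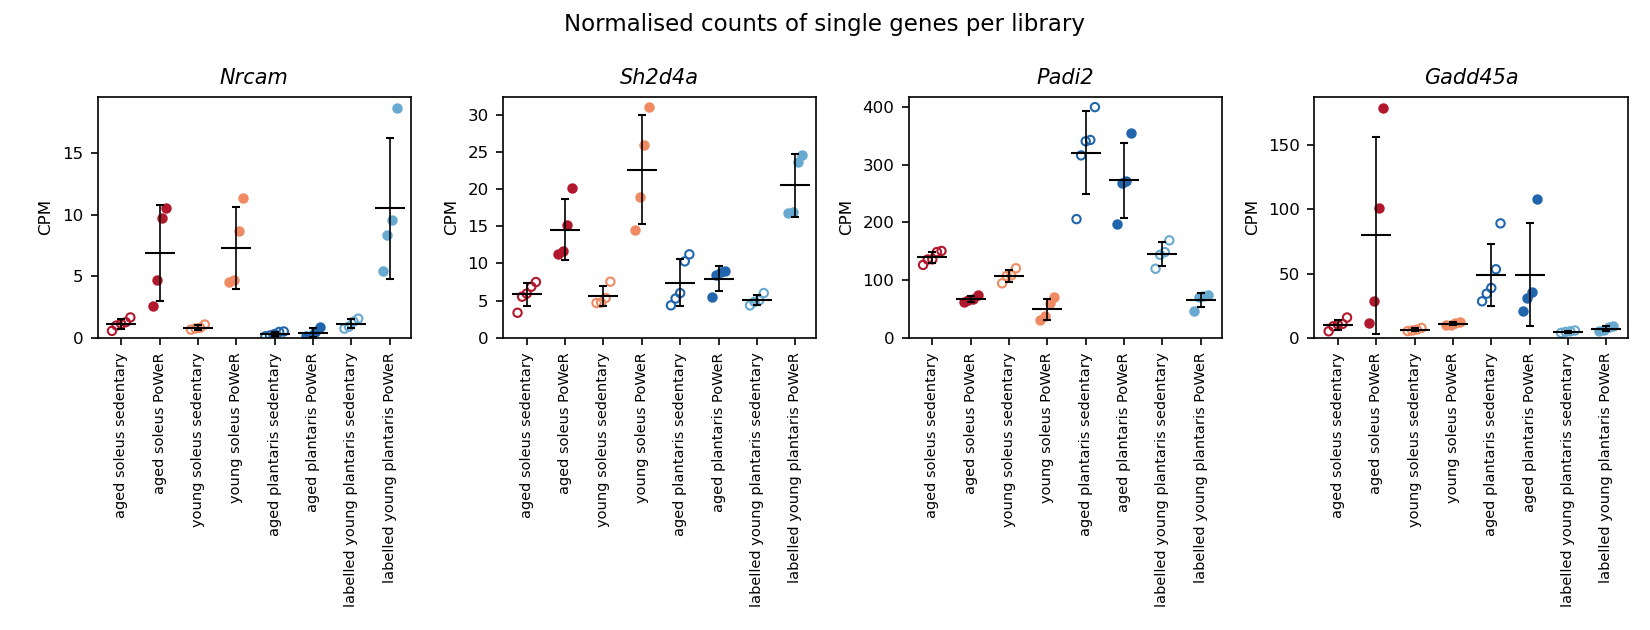
CPM of Nrcam, Sh2d4a, Padi2 and Gadd45a in each library of the 8 groups; points are libraries (filled for PoWeR), horizontal marks the mean and bars the SD. In both soleus comparisons and in the libraries labelled young plantaris every PoWeR library lies above every sedentary library for Nrcam and Sh2d4a and below for Padi2, while Gadd45a in aged soleus PoWeR runs from 11.3 to 179.

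Whether training acted differently at the 2 ages was tested by the age by PoWeR interaction. In soleus the strongest differences were those of the signalling gene Wls (-0.78 ± 0.14, SE; aged effect minus young effect), Lnpk (-0.86 ± 0.16), Dusp1 (-1.73 ± 0.32) and Lrrk2 (-1.23 ± 0.24) downward, and of the kinase gene Pim1 (1.37 ± 0.26), the growth factor gene Gdf5 (6.56 ± 1.31), Iqcg (1.99 ± 0.43) and Rbis (1.14 ± 0.25) upward, none past the adjustment. Of the 128 genes called in aged soleus, 112 had the same sign in young soleus, where 31 were also called higher and 26 lower. Independent lists would give 4.18 and 4.0, and 0 genes were called in opposite directions. Nrcam, Sh2d4a, Rrm2, Serpinb1a, Padi2, Ostn, Acaa2, Acadm and Gabarapl1, an autophagy gene, were among the genes called at both ages.

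By edgeR 0 of 14934 genes had an interaction in soleus (smallest adjusted p = 0.119), with 1995 at an unadjusted p under 0.05, 72 by DESeq2 and 0 by limma; without young PoWeR replicate 4 the edgeR count was 58, without young sedentary replicate 4 it was 1, and without aged PoWeR replicates 14 or 15 it was 2 or 3. Across genes, which are not independent replicates, the fold changes at the 2 ages had a Pearson r of 0.20 and a Spearman rho of 0.27. In simulated data with known answers edgeR recovered 50 of 100 changes of 2-fold for this interaction and 14 of 100 of 1.5-fold, with 3.03% of its calls false; 13% of the calls by DESeq2 were false there.

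**Figure D5:**
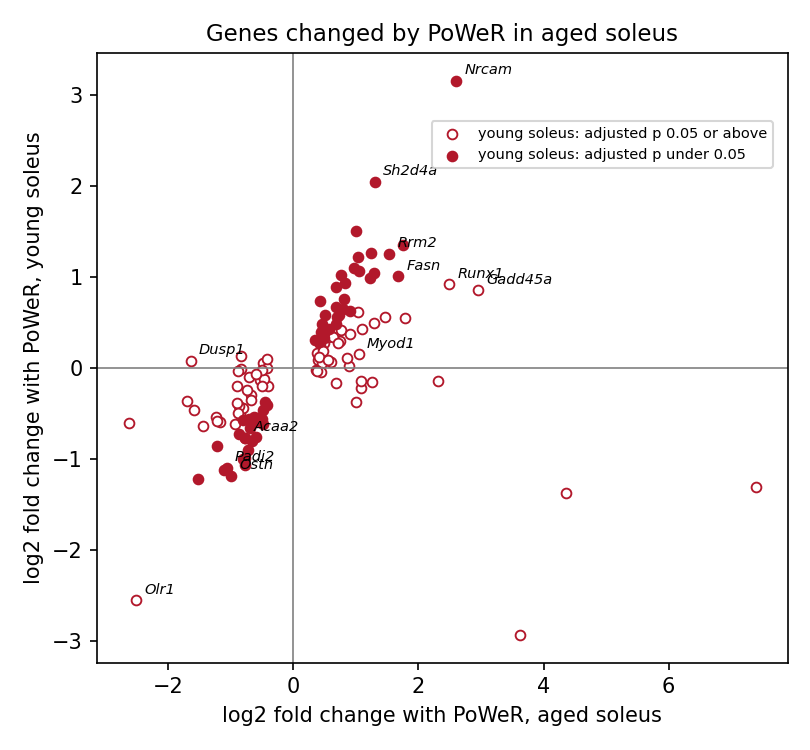
Log2 fold change with PoWeR in aged (x axis) and young soleus (y axis) of the 128 genes called in aged soleus; filled points passed the test in young soleus too. Of the 128 points 112 have the same sign at both ages.

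In plantaris the interaction sets aged plantaris against the libraries labelled young plantaris, so that it mixes age with their soleus-like profile. Tjp1 (0.96 ± 0.18, SE) and Sh2d4a (-1.90 ± 0.36) were among the strongest differences. Sh2d4a had a log2 fold change of 0.10 in aged plantaris and 2.0 in the libraries labelled young plantaris. By edgeR 0 of 15280 genes passed (smallest adjusted p = 0.112), with 1737 at an unadjusted p under 0.05, 96 by DESeq2 and 156 by limma. The fold changes had an r of 0.0362 across genes. Without sedentary replicate 1 of the libraries labelled young plantaris the edgeR count was 3, and without sedentary replicate 4 or PoWeR replicate 3 it was 1.

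Whether training acted differently in the 2 muscles was tested within each age. In aged mice Tjp1 (-0.98 ± 0.18, SE; soleus effect minus plantaris effect), the cytochrome oxidase subunit Cox8b (-1.01 ± 0.21) and the carbonic anhydrase Car2 (-1.09 ± 0.22) were among the strongest differences downward, and Tnip1 (1.02 ± 0.21) was the strongest upward. By edgeR 0 of 14823 genes passed (smallest adjusted p = 0.116), with 1785 at an unadjusted p under 0.05, 183 by DESeq2 and 42 by limma. The edgeR count was 197 without aged plantaris PoWeR replicate 10 and 2 without aged plantaris sedentary replicate 15. It was also 2 with the replicate numbers of the labels as a block. The effects in the 2 aged muscles had an r of 0.0482 across genes. In young mice young soleus and the libraries labelled young plantaris had an r of 0.47. Of the 34 genes called in the latter, 34 had the same sign in the former. In both, 18 were higher (1.39 for independent lists) and 10 lower (0.771). The library names of these 2 sets share numbers, so they may come from the same mice and not be independent. By edgeR 0 of 15132 genes had an interaction there (smallest adjusted p = 1.0), with 445 at an unadjusted p under 0.05, 0 by DESeq2 and 0 by limma.

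Age was compared in sedentary soleus. Mitochondrially encoded genes were lower in aged mice in 13 of 13 cases (mean log2 -1.26), led by mt-Nd4l (-2.31 ± 0.23, SE), mt-Nd3 (-1.81) and mt-Nd5 (-1.78). Tendon genes were lower in 8 of 8 (-1.96), with the proteoglycan genes Kera (-4.16 ± 0.48) and Fmod (-2.96 ± 0.40) and the transcription factor gene Mkx (-2.27) ahead, and the collagen genes Col1a1 (-1.99 ± 0.45) and Col1a2 (-1.86) were among 4 of 24 matrix genes that were lower. Antioxidant genes were higher in 8 of 17 and lower in 1, with Srxn1 (1.20 ± 0.12), Gstm1 (1.08) and the glutathione synthesis gene Gclc (1.04) highest. Fatty acid use genes were higher in 11 of 22 and lower in 1, including the lipid droplet gene Plin5 (0.93), Pdk4 (0.75), Ucp3 (0.72) and the carnitine transferase Cpt1b (0.68).

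In total 5411 of 14934 genes differed by edgeR, 2914 higher and 2497 lower in aged soleus. The largest rises were those of Fbxo44 (5.07 ± 0.32), the nuclear noncoding RNA Neat1 (5.02 ± 0.34), Rab6b (4.27), Rgs11 (3.74), Olr1 (3.68), Rsrp1 (3.49), Leng8 (3.38) and Lgals4 (3.18). Neat1 had 2961 ± 266 CPM (SD, n = 5) in aged and 94.3 ± 25.6 CPM (n = 4) in young sedentary soleus. The largest falls were those of Gdpd3 (-3.89), Rbp7 (-3.26), the cartilage and tendon genes Cilp2 (-3.25) and Chad (-3.15), Fmod and the small noncoding RNAs Rn7s2 (-3.34), Rn7s1 (-3.15) and Rn7sk (-3.02); Rn7s1 and Rn7s2 are near-identical copies whose reads cannot be told apart. Vegfa was higher in aged mice (1.18 ± 0.16), while Angpt1 (-1.28) and the apelin receptor gene Aplnr (-2.08) were lower. The clock genes Arntl (1.96 ± 0.18) and Npas2 (2.02) were higher and Hlf (-1.63), Dbp (-1.54), Per2 (-1.07) and Tef (-0.39) lower. The call of Dbp was kept in 3 of 9 fits that left out a library. It was lost with no low count filter and with only the 2 groups compared. Myh1 (1.85 ± 0.51) was higher too. The call of Myh4 (4.10 ± 1.42) rests on aged sedentary replicate 13, at 1596 CPM beside 13.9 to 100 CPM in the other aged and 14.1 to 24.8 CPM in the young libraries; it was lost without that replicate and kept in 4 of 9 fits that left out a library. Of 38 lists 5 passed camera, the 5 named in the preceding paragraph, with a smallest adjusted p = 0.723 with an estimated correlation; fry passed 7. Every aged library differs from every young library in age and in whatever else separates the cohorts, so that the labels cannot part them.

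The same comparison in plantaris set aged plantaris against the libraries labelled young plantaris and gave the pattern of a fast against a slow muscle. All 12 slow fibre genes were lower (mean log2 -4.58), with Myh7 at -5.63 ± 0.73 (SE) and the slow calcium pump Atp2a2 at -5.73 ± 0.49. All 15 fast fibre genes were higher (3.75), with Myh4 at 10.92 ± 0.49 and the calcium buffer Pvalb at 7.31 ± 0.56, and 16 of 18 glycolysis genes were higher. Mitochondrial biogenesis genes were lower in 8 of 13, endothelial genes in 8 of 12, tendon genes in 7 of 8, angiogenic genes in 6 of 9 and matrix genes in 6 of 24. By edgeR 7625 of 15280 genes differed, 3820 higher and 3805 lower; 9 of 39 lists passed camera, with a smallest adjusted p = 0.242 with an estimated correlation. Because the young group of this comparison is soleus-like, these values do not measure age within the plantaris.

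Myosin heavy chain composition was compared as each gene's share of the counts of Myh1, Myh2, Myh3, Myh4, Myh7 and Myh8. In aged plantaris Myh4 held 69.4 ± 7.43% (SD, n = 5) in sedentary and 49.8 ± 15.3% (n = 4) in PoWeR mice, and Myh1, the heavy chain of IIx fibres, held 21.6 ± 4.25% and 35.1 ± 8.50%. Each had an exact two-sided permutation p of 0.0317, and an adjusted p of 0.254 over 16 tests, so neither passed; 3 of 4 PoWeR libraries lay beyond all sedentary libraries in each. In aged soleus Myh7 held 52.7 ± 2.67% and 57.6 ± 4.84% (exact p = 0.0635). In young soleus it held 66.3 ± 3.03% and 69.6 ± 4.79% (exact p = 0.257), and in the libraries labelled young plantaris 67.8 ± 2.43% and 69.4 ± 2.62% (exact p = 0.40). The smallest p the design allows is 0.0159 with 5 and 4 libraries and 0.0286 with 4 and 4.

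Finally, the effect of PoWeR in aged mice was set against the difference with age, which use the same aged sedentary libraries. In soleus the covariance of the fold changes across genes was -0.0425, beside -0.0429 in simulated unchanged groups, and -0.0041 when the aged sedentary libraries were divided between the comparisons. Signs were opposite in 53.6% of genes, beside 64.6% in simulated unchanged groups, so shared libraries alone give opposite signs. Of the 128 genes called with PoWeR 10 were higher in both (13.7 for independent lists, which leaves out the shared libraries) and 8 lower in both (9.70). Another 53 were called in opposite directions, and 44 of the 128 had the sign of the age difference. In plantaris the covariance was -0.225, beside -0.0592 in simulated unchanged groups and -0.173 with divided controls, again against the libraries labelled young plantaris.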

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

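The tests of the muscle profile, of the GC and length offsets, of the clock genes and of the rRNA repeat share were chosen after the results were seen; the splits of the samples and the test of a batch in young soleus were set beforehand.

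All 8 libraries labelled young plantaris have a soleus-type profile. On an index from 0 (aged sedentary soleus) to 1 (aged sedentary plantaris) over 1700 genes their median was 0.114, as a wrong muscle label would give, and that of young soleus was 0.112, which argues against a swap of labels within the young libraries. A change limited to fibre type genes is argued against by 0.995% of 1508 other muscle-differing genes that differ the same way in the young libraries. Aged libraries labelled by muscle differ in 4871 genes and young ones in 493. A wrong label is a candidate explanation; that the plantaris of young mice truly has this profile was not tested by any other data.

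Aged and young sedentary soleus differ in 5411 genes, including clock genes. Of these, 88.2% kept their call with GC and length offsets, and for 83.7% the libraries labelled young plantaris lay nearer to young soleus than to aged soleus, which argues against gene composition and against a batch of the young soleus libraries alone. The activating and the output arms of the clock differ by 2.03 in mean log2 fold change (Arntl 1.96 and Npas2 2.02 against Dbp -1.54 and Hlf -1.63), as a different time of collection could give, although Clock (0.31), Per1 (0.26), Per3 (0.30), Nr1d1 (-0.16) and Nr1d2 (-0.19) were not called. Age cannot be told apart from cohort or hour of collection in these libraries, since the labels give neither of the last. A biological difference with age remains among the open explanations.

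Genes of oxidative phosphorylation and ribosomal proteins had lower values with PoWeR in young soleus and in the libraries labelled young plantaris. In young soleus the mean of the 45 members went from -0.57 to -0.47 with GC and length offsets, so gene composition is not the whole cause. Calls among them went from 38 to 34. With a term for the rRNA repeat share the mean was -0.45 and 25 members were called lower. That term marks a single soleus library, young PoWeR replicate 3, so it acts like leaving that library out and cannot test a library batch. In the libraries labelled young plantaris the mean went from -0.34 to -0.0592 with the rRNA repeat term, so a library batch is a candidate explanation there. In that group 3 of 4 PoWeR and 1 of 4 sedentary libraries have the low share, which leaves training and batch poorly separated. An effect of training stays open in both.

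Other splits of the libraries were compared with the real groups. The real grouping is itself 1 of the splits, so 1 of 100 or 1 of 35 is the smallest share they allow. No adjustment was made over the comparisons. Chance is argued against for PoWeR in aged soleus, where 1 of 100 splits, the real one, gave as many genes (128, highest other 10). It is also argued against for PoWeR in young soleus (1 of 35 splits, 1920 genes, highest other 115). The same holds of chance for age in soleus (1 of 100, 5411 genes, highest other 2652) and in plantaris (1 of 100, 7625 genes, highest other 4905). Chance cannot be excluded for PoWeR in aged plantaris (9 of 100 splits, 4 genes, highest other 108), where the highest split points to a structure of those libraries apart from training. By the splits alone it cannot be excluded for the libraries labelled young plantaris either (2 of 35 splits, 34 genes, highest other 1265). The highest split there follows the rRNA repeat share. With a term for that share a single gene passed, although Padi2 and Vegfa still lay apart between libraries of like share. Of the 34 genes, 34 had the same sign in young soleus. In both, 18 were called higher and 10 lower, beside 1.39 and 0.771 for independent lists. The library names of the 2 sets share numbers, so the same mice may have given both. This overlap therefore cannot decide whether chance gave these genes. For the muscle by PoWeR interaction in aged mice the real groups gave the most genes at an unadjusted p under 0.05 (1 of 100 splits, 1785 genes, highest other 1686). The margin is small, and 0 genes pass the adjustment by edgeR. Splits for an interaction regrouped PoWeR and sedentary libraries within each muscle or age. They thus test for no PoWeR effect in either, not for an equal effect in both, and cannot decide on an interaction. Chance is not firmly excluded for the age by PoWeR interaction in soleus (4 of 100; 1995, highest other 3316), since other splits gave more genes and 0 pass the adjustment. It cannot be excluded for the age by PoWeR interaction in plantaris (5 of 100; 1737, highest other 2436) or for the muscle by PoWeR interaction in young mice (59 of 100; 445, highest other 3782), and the last points to structure among the young libraries.

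In 14 of 128 groups of values tested a single library stood far from the others; chance does so in about 1 in 20 groups. In aged soleus sedentary replicate 13, fast fibre genes were high: Myh4 at 1596 CPM (13.9 to 100 CPM in the others), Mybpc2 at 166 CPM, Actn3 at 364 CPM and a Myh4 share of 3.15% of myosin counts. Sedentary replicate 14 of that muscle had a Myh2 share of 43.5%, and PoWeR replicate 14 had Tnnt1 at 3436 CPM. Aged plantaris sedentary replicate 16 had Mybpc2 at 9267 CPM and a Myh2 share of 2.14%, and aged plantaris PoWeR replicate 15 had a total of 21378026 counts. Young soleus sedentary replicate 2 had Tnni1 at 1387 CPM, sedentary replicate 4 an rRNA repeat share of 1.27%, and PoWeR replicate 3 Malat1 at 1631 CPM. Among the libraries labelled young plantaris, PoWeR replicate 3 had an rRNA repeat share of 2.73% and PoWeR replicate 4 Malat1 at 1284 CPM.

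Gene lists differed between groups in the effect of PoWeR in 39 tests of the difference by camera with its preset correlation; with an estimated correlation 0 did (smallest adjusted p = 0.117). In soleus the aged minus young effect was 0.28 for nuclear oxidative phosphorylation, 0.27 for mitochondrially encoded genes, 0.18 for the TCA cycle, 0.43 for endothelial, 0.56 for interferon, 0.58 for Schwann cell, 0.50 for integrated stress, 0.46 for ribosomal protein and 0.33 for antioxidant genes. In plantaris, against the libraries labelled young plantaris, it was 0.63, 0.92 and 0.36 for the first 3 of these lists, 0.28 for fatty acid use, 0.75 for angiogenic factors, 0.75 for endothelial, 1.66 for Schwann cell, 1.81 for adipocyte, 0.64 for smooth muscle, 0.36 for ribosomal protein, -0.71 for atrophy and -0.29 for glucocorticoid genes. In aged mice the soleus minus plantaris effect was 1.33 for denervation, 0.56 for atrophy, 0.50 for glucocorticoid, 0.22 for ribosome biogenesis and 0.18 for autophagy genes. It was -0.65 for slow fibre, -0.57 for oxidative phosphorylation, -0.95 for mitochondrially encoded, -0.36 for TCA cycle, -0.27 for fatty acid use, -0.43 for angiogenic, -0.75 for fibro-adipogenic and -0.78 for smooth muscle genes. In young mice, against the libraries labelled young plantaris, it was -0.23 for oxidative phosphorylation, -0.32 for mitochondrially encoded, -0.20 for TCA cycle, -0.29 for ribosomal protein and -0.19 for antioxidant genes.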

How the results depend on the processing

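The GC and length offsets, the rRNA repeat term and the omission of 2 distinct aged plantaris libraries (sedentary replicate 16 and PoWeR replicate 12) were chosen after seeing the data. The other alternatives were set beforehand. The rRNA repeat term marks no aged library, and in soleus only young PoWeR replicate 3. The cause of a change was not tested unless stated.

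Counts of genes changed by PoWeR in aged soleus (128) became 378 with DESeq2, 521 with limma and quality weights, 216 with the rRNA repeat term, 229 with only the 2 groups compared and 71 with the replicate block, of which 28 were shared. Leaving out single libraries gave 36 to 172. In aged plantaris the 4 genes became 2 with no filter, 116 with DESeq2, 8 with the rRNA repeat term, 0 with only the 2 groups compared (edgeR; 1214 at an unadjusted p under 0.05), 0 with the replicate block (671) and 8 with the 2 distinct libraries left out, and 0 to 10 without single libraries. In young soleus the 1920 genes became 620 with the rRNA repeat term, 358 with only the 2 groups compared and 602 to 2545 without single libraries. In the libraries labelled young plantaris the 34 genes became 222 with DESeq2, 1369 with limma and quality weights, 1 with the rRNA repeat term, 87 with only the 2 groups compared and 1 to 227 without single libraries. The replicate numbers of the labels were checked before being used as pairs: residuals of soleus and plantaris libraries with the same number correlated at 0.0482 to 0.462 across genes (median 0.27; 8 of 9 over 0.1, and 8 of 9 best with their own number), a hint from the data that these muscles are paired. Those of sedentary and PoWeR libraries correlated at -0.291 to 0.169 (1 of 6 over 0.1). Since not every pair was over 0.1, the main fits stayed unpaired.

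The interactions, 0 by edgeR, were 72 with DESeq2 and 0 to 58 without single libraries for age by PoWeR in soleus (1995 at an unadjusted p under 0.05). For age by PoWeR in plantaris they were 96 with DESeq2, 156 with limma and quality weights, 9 with all 8 groups in the fit, 1 with the 2 distinct libraries left out and 0 to 3 without single libraries. For muscle by PoWeR in aged mice they were 183 with DESeq2, 42 with limma, 3 with all 8 groups, 2 with the replicate block and 0 to 197 without single libraries.

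Gene lists that reversed were, in aged plantaris with the 2 distinct libraries left out, extracellular matrix (-0.15), fibro-adipogenic (-0.22) and adipocyte genes (-0.40), and the adipocyte list in the age by PoWeR interaction there (-0.16). Mitochondrially encoded genes in the libraries labelled young plantaris reversed to 0.0323 with the rRNA repeat term. The number of lists past camera was 0 in all 10 comparisons with an estimated correlation. It was 15 in aged soleus and 14 for age in plantaris with no filter. With the replicate block it was 15 in aged soleus and 21 for muscle by PoWeR in aged mice. With the rRNA repeat term it was 0 in the libraries labelled young plantaris and 12 for muscle by PoWeR in young mice, and with only the 2 groups compared 19 in the libraries labelled young plantaris. Without single libraries it was 8 to 14 in aged soleus, 6 to 14 for age by PoWeR in soleus, 5 to 16 for muscle by PoWeR in aged and 1 to 10 in young mice.

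Correlations over genes above 5 CPM were 0.41 for the ages in soleus, 0.0399 in plantaris, 0.0897 for the muscles in aged and 0.77 in young mice. Covariances of age and PoWeR effects were -0.00797 in soleus and -0.117 in plantaris over such genes, and -0.00406 and -0.173 with divided controls. As CPM in place of a share, Myh2 differed by 769 and Myh1 by 194 CPM in young soleus, and Myh2 by 782 CPM in the libraries labelled young plantaris, each opposite to its share. Without single libraries the difference in share (percentage points) ran from -3.51 to 3.15 for Myh1 and -0.297 to 0.481 for Myh4 in aged soleus, from -1.09 to 1.29 for Myh1 in young soleus, and from -2.84 to 1.07 for Myh2 and -2.77 to 0.549 for Myh1 in the libraries labelled young plantaris.

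Over all alternatives, those above included, the direction and side of the threshold stayed the same for 1926 of 2269 values of named genes (343 lost their call), 1530 of 1827 of gene lists (292 lost it), 138 of 152 of myosin shares, 148 of 175 numbers of lists, and 173 of 238 counts and correlations. No list was tested with the GC and length offsets, since voom takes no offsets. Depth was not varied; replicates differed by more than counting error in every group (smallest chi-square per degree of freedom 4.90).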

Other observations

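The per library values of the denervation genes, Krt8, Krt18 and Gdf5 were chosen after the results were seen; no explanation was tested for them.

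In aged soleus the denervation genes, which muscle fibres turn on when they lose contact with their nerve, differed among the PoWeR libraries. Mean log2 values over 11 genes, relative to the sedentary mean, were 1.84, 1.99, -0.19 and 0.77 in PoWeR replicates 10, 12, 14 and 15, and lay between -0.16 and 0.45 in the 5 sedentary libraries. Counts of Runx1 were 580, 691, 56 and 161 in the PoWeR libraries and 49 to 78 in the sedentary ones. Counts of Chrng, the fetal subunit of the acetylcholine receptor, were 108, 53, 5 and 26, against 4 to 17. Keratin genes followed the same libraries: Krt8 had 131, 67, 3 and 25 counts against 0 or 1, and Krt18 had 269, 514, 12 and 133 against 2 to 30. Gdf5, a growth factor gene of the BMP family, had 178, 200, 9 and 55 counts against 0 to 15. The log2 fold changes were 7.40 for Krt8 (edgeR adjusted p = 0.0107), 4.35 for Krt18 (0.0163) and 3.63 for Gdf5 (0.0292). PoWeR replicate 14 lay within the sedentary range for Runx1, Chrng, Krt18 and Gdf5.

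Some heat shock and autophagy genes were higher in aged than in young sedentary soleus, where 36.2% of all genes differed; neither list passed camera. Hspa1a (1.10 ± 0.20, SE), Hspb1 (0.85 ± 0.18) and Cryab (0.79 ± 0.16) were among 7 of 15 heat shock genes that were higher, while 2 were lower; reads of Hspa1a and its neighbour Hspa1b are hard to tell apart. The autophagy receptor Sqstm1 (0.43) and Map1lc3b (0.41) were among 5 of 14 autophagy and lysosome genes that were higher. The coactivator gene Ppargc1a (-1.05 ± 0.28) and the receptor genes Esrra (-0.59) and Esrrg (-0.61) were lower among 13 mitochondrial biogenesis genes. The immediate early gene Fos was higher (2.36 ± 0.55) and Nr4a3 lower (-1.56). Sarcomere genes that respond to load went both ways, with Xirp1 (0.80), Flnc (0.76) and Ankrd2 (0.68) higher and Xirp2 (-0.87) lower. With PoWeR in young soleus Xirp2 rose (0.96 ± 0.24), and the stress cytokine gene Gdf15 fell (-2.33 ± 0.63).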
